A study of Mus musculus with 10 samples.

How the data were processed

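Total RNA from mouse C2C12 myotubes was hybridised to Affymetrix arrays, 1 array per sample. C2C12 is a mouse myoblast line that fuses into multinucleated myotubes when serum is lowered. Per the labels' protocols, the cells were differentiated for 2 days in 2% horse serum and exposed for 48 h, at a multiplicity of infection of 100, to adenovirus that carried a short hairpin RNA against Zc3h10 or a scrambled hairpin. The labels give 3 µg of total RNA for labelling. The 10 arrays formed 2 groups of 5, named here shZc3h10 and Scr. The cell line field of the labels reads C2C12 while the sample titles spell it C1C12, and the former was followed. The labels do not say whether the 5 samples of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical.

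The authors deposited 1 table of log2 expression values for 41345 probe sets on the 10 arrays. The submitters' processing notes name Affymetrix Expression Console, Partek 6.6 and RMA, a method that corrects background, normalises between arrays and summarises the probes of a probe set, without saying which tool did which step. The deposited values ran from about 2.07 to 14.64, with array medians between 6.68 and 6.75, as log2 values normalised between arrays would. A test used by the submitters and a genome build are not given in the sources used here, so no coordinates are printed. RMA values at the low end approach the background, and those at the high end approach saturation, so that fold changes are understated at both ends. The number of arrays limits the precision.

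Probe sets were named from a platform annotation table that listed 25335 of them. Of these, 23521 carried 1 gene symbol and 1814 carried several, and 16010 probe sets of the deposited table were not named there. The Entrez identifiers of 23328 single-symbol probe sets were found in the RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 of them had another symbol there. Each gene was represented by its probe set with the highest mean over all arrays, which mattered for 1082 genes with more than 1 probe set. This left 22180 genes, and no filter on low values was applied. Probe sets without a single symbol were tested in a fit of all 41345 probe sets, with adjustment over all of them, and were counted apart from the genes.

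Genes were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as shZc3h10 minus Scr over all 10 arrays, two-sided, with Benjamini-Hochberg adjustment over the 22180 genes. A gene is said to have risen or fallen where its adjusted p was under 0.05. Values are given as log2 differences with their moderated standard error (SE), and levels as mean ± SD over 5 arrays. Named genes followed a rule. It takes Zc3h10, then the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out predicted models and olfactory, vomeronasal, histone cluster, immunoglobulin and T cell receptor genes, and then up to 3 called genes of smallest p in each gene list, or the gene of smallest p where none was called. Other genes named from a list were chosen after their values were seen.

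The 29 gene lists and 7 lists of cell type markers were written before the data were examined, as were the tests and the alternative settings. They cover the mitochondrial respiratory chain, ribosome, import, dynamics, biogenesis and encoded genes, the TCA cycle, fatty acid oxidation, glycolysis, cholesterol biosynthesis, the sarcomere, excitation-contraction coupling, myogenic regulators, the cell cycle, the proteasome, cytosolic ribosomal proteins, endoplasmic reticulum chaperones, the extracellular matrix, interferon, NF-kB, p53, NRF2, hypoxia, iron, stress response, immediate early and atrophy genes. The markers were those of myoblasts, fibroblasts, adipocytes, macrophages, endothelium, osteoblasts and smooth muscle. Of 1004 list members, 905 were measured. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 36 lists, and again with the correlation estimated per list. Each list's median was also set against 10000 random lists of the same size matched on expression level in 20 bins. A list that shifts by little can pass the test because its genes are precise, so the number of genes that rose or fell stands beside each test.

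The procedure was tested on simulated data with the means and spreads of the Scr arrays for 22180 genes in 5 against 5 arrays. It recovered 48.5% of genes changed 1.25-fold, 90.9% of those changed 1.5-fold and 98.5% of those changed 2-fold. Only 66, 66 and 68 genes were changed at these folds, whereas 25% of genes were called in the real data. The adjustment is stricter where fewer genes change, so these recovery rates do not carry over to the real data. Of 21950 unchanged genes, 17 were called, which was 8.99% of all calls. A simulated list of 30 genes shifted by 0.2 was called by camera, and an unchanged list of that size was not. The simulated genes were drawn independently of each other, so this does not test camera on lists whose genes vary together.

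The alternatives were the replicate number as a block, trended and robust moderation, array weights, an ordinary linear model, quantile normalisation, median centring, cyclic loess, a filter on dim genes, the mean of a gene's probe sets, every probe set, a fold of at least 1.5, an adjusted p under 0.01, other tests of the lists (fry and an exact permutation) and leaving out each array in turn.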

Results

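The series profiled gene expression in C2C12 myotubes that received a hairpin against Zc3h10, a CCCH-type zinc finger protein that the study's title presents as a mitochondrial regulator, and in control myotubes. Each of 5 samples received an adenoviral short hairpin against Zc3h10 (shZc3h10) and each of 5 others a scrambled hairpin (Scr). The 10 arrays had medians between 6.68 and 6.75 on the log2 scale and highest values between 14.60 and 14.64. Over all probe sets, arrays correlated at 0.990 to 0.994 within Scr, 0.994 to 0.995 within shZc3h10 and 0.989 to 0.992 between the groups. The groups separated along the first principal component, which held 41.4% of the variance, with Scr at -15.0 to -14.1 and shZc3h10 at 14.1 to 16.1. Along the second component, with 11.2%, Scr 2 lay at -20.4 while the other arrays lay between -2.8 and 9.7. Without Scr 2, 2730 genes were higher and 2810 lower, against 2763 and 2785 with it.

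Zc3h10 itself was lower in shZc3h10. Its probe set, 17246198, is the only one that carries its symbol, and it read 7.69 ± 0.0933 in Scr and 7.48 ± 0.114 in shZc3h10 (SD, n = 5 each). The log2 difference of -0.21 (SE 0.0628, limma adjusted p = 0.028) is a fall of 13.8%. The groups overlapped, since the lowest Scr array read 7.56 and the highest shZc3h10 array 7.61. The call was lost when Scr 4, Scr 5, shZc3h10 1, shZc3h10 2 or shZc3h10 4 was left out (adjusted p = 0.0659 to 0.0698), and with the replicate number as a block (adjusted p = 0.0678). Among called genes, 1732 fell by more than Zc3h10 did.

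Many genes differed between the groups by modest amounts. Of 22180 genes, 2763 were higher and 2785 lower in shZc3h10, together 25% of genes, with a median size of 0.251 on the log2 scale. Calls were more frequent at higher signal levels. With the genes in 10 equal parts by level, 81 rose and 100 fell in part 4, at a mean of 6.285. In part 9, at a mean of 10.14, 529 rose and 574 fell. Counts within lists are therefore to be read against genes of similar level. A change of at least 1.5-fold was reached by 122 of the genes that rose and 242 of those that fell, and a change of at least 2-fold by 11 and 37. In 4956 genes (22.3%) the groups did not overlap, where chance gives 0.794%.

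Muscle genes were among the largest falls. Myh4, the fast type IIb myosin heavy chain, fell by 2.11 from 11.27 ± 0.0699 to 9.16 ± 0.162 (SE 0.0731, adjusted p = 3.72e-08), and Casq1, the calcium store protein of fast fibres, fell by 2.00 from 10.45 ± 0.0979 to 8.45 ± 0.0484 (SE 0.0497, adjusted p = 1.17e-08). Mybpc2, a fast myosin-binding protein, fell by 1.57, the calcium buffer Pvalb by 1.47 and Tmod1, which caps thin filaments, by 1.42. Myoz1, a Z-disc protein, went from 8.13 ± 0.173 to 6.63 ± 0.0974. Hspb7, a small heat shock protein of muscle, fell by 1.56. Gpd1, a cytosolic glycerol-3-phosphate dehydrogenase, fell by 1.80. The germ cell transcription factor gene Sohlh2 fell by 1.92, the copper-containing ferroxidase gene Hephl1 by 1.67, the tetraspanin gene Tspan32 by 1.45 and Trp63, a relative of p53, by 1.39. These 12 genes had SEs of 0.0396 to 0.109, and their groups did not overlap on any of the 10 arrays.

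The largest rise was that of Gbp8, an interferon-inducible guanylate-binding GTPase, by 1.69 from 9.04 ± 0.159 to 10.73 ± 0.0533 (SE 0.0699, adjusted p = 9.13e-08). Its relatives Gbp4 and Gbp9 were up by 1.07 and 1.06, and Apol9b, an apolipoprotein L gene, by 1.07. Cnn1, calponin of smooth muscle, rose by 1.65 from 7.22 ± 0.164 to 8.87 ± 0.202 (SE 0.104, adjusted p = 1.32e-06). Psrc1, a spindle protein gene, was up by 1.17, Hoatz, a gene of motile cilia, by 1.12, Camk1g by 1.01, Fxyd5 by 1.01, Sh3gl3 by 0.96 and the metalloprotease gene Adamts16 by 0.93. Zfp457 was up by 1.17 but its probe set was dim, at 4.47 ± 0.489 in Scr. Probe sets of Gbp, Apol9 and Zfp genes may also bind close relatives, so the member that changed is uncertain.

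**Figure D1:**
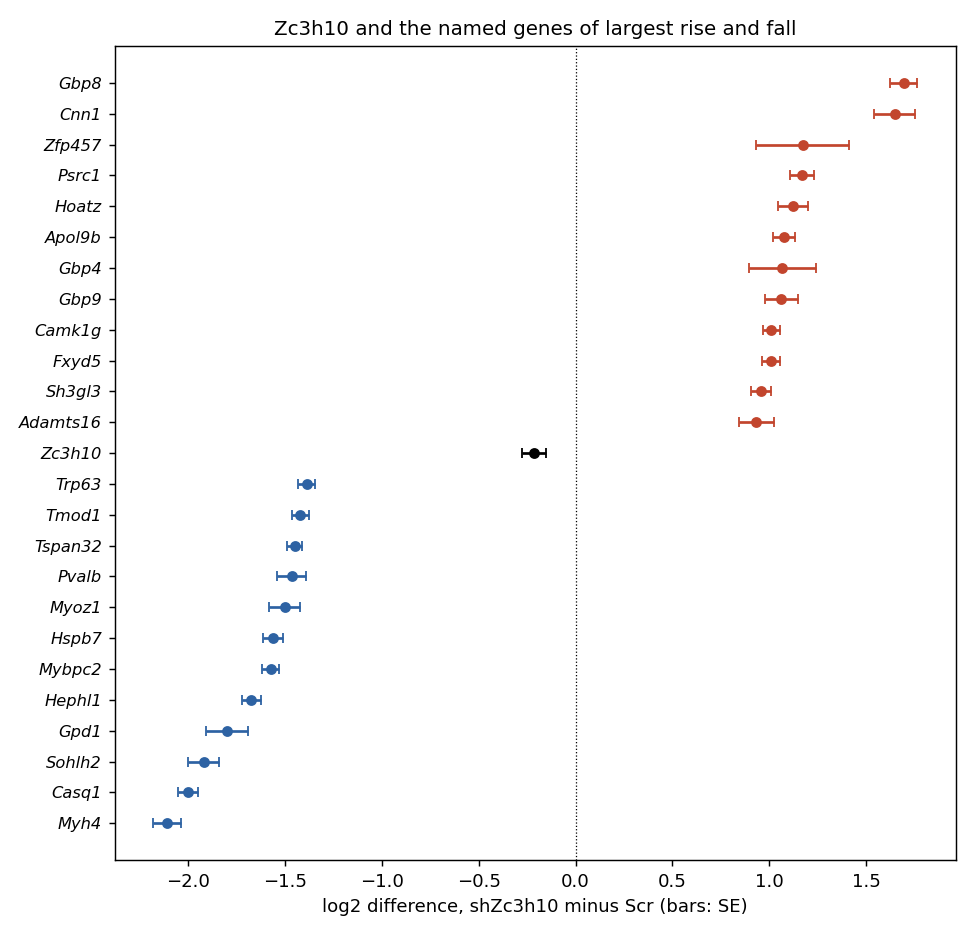
Log2 difference (shZc3h10 minus Scr, horizontal axis) with its SE for Zc3h10 (black) and the 12 named genes of largest rise (red) and 12 of largest fall (blue), 5 arrays per group. Zc3h10 lies at -0.21, between the falls of -2.11 to -1.39 and the rises of 0.93 to 1.69.

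Contractile genes fell as a group. Of 53 sarcomere genes measured, 43 fell, 4 rose and 6 did not pass (43 fell and 5 rose adjusted over the list alone), with a median difference of -0.36 (camera adjusted p = 4.93e-23, and adjusted p = 0.0106 with an estimated correlation). Beside Myh4 and Mybpc2, Actn2, the Z-disc alpha-actinin, fell by 1.33 (SE 0.041, adjusted p = 1.86e-08), the perinatal and slow myosins Myh8 and Myh7 fell by 1.29 and 1.05, and Mb, myoglobin, fell by 0.94. Ttn and Acta1 fell by 0.34 and 0.27. The 4 that rose were Nebl (0.61), Tpm3 (0.30), Tpm1 (0.25) and Cryab (0.10), which are also expressed outside skeletal muscle. Myosin heavy chain genes share sequence, so their probe sets may not separate them fully. In the list of excitation-contraction coupling and the neuromuscular junction, 23 of 31 genes fell, 2 rose and 6 did not pass (24 and 2 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 5.33e-12, and adjusted p = 0.0476 with an estimated correlation). Atp2a1, the calcium pump of fast fibres, fell by 0.60 (SE 0.031, adjusted p = 3.61e-07), and the ryanodine receptor gene Ryr1 fell by 0.33, whereas Asph and Lrp4 were up by 0.28 and 0.22.

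Regulators of myogenesis moved in both directions. Of 33 measured, 14 fell, 5 rose and 14 did not pass (15 and 5 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.0444, and adjusted p = 0.128 with an estimated correlation). The list's call was also lost when Scr 2, Scr 5, shZc3h10 4 or shZc3h10 5 was left out (adjusted p = 0.0515, 0.0659, 0.0513 and 0.0518), and with the replicate block, array weights, quantile normalisation or the filter on dim genes (adjusted p = 0.0507 to 0.0699). Mymx, the fusion peptide myomixer, fell by 0.81 (SE 0.0318, adjusted p = 7.54e-08), Myf6 fell by 0.74 (SE 0.0522, adjusted p = 2.56e-06), and Myog, Myod1 and Mef2c fell by 0.44, 0.36 and 0.35. Mstn, myostatin, fell by 1.07. Myf5, a factor of undifferentiated myoblasts, went the other way and rose by 0.47 (SE 0.0388, adjusted p = 7.12e-06).

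Most of the measured proliferation genes rose. In the list of the cell cycle and DNA replication, 45 of 50 genes rose, 1 fell and 4 did not pass (46 and 2 adjusted over the list alone), with a median of 0.41 (camera adjusted p = 2.01e-23, and adjusted p = 0.037 with an estimated correlation). Ccnb2, a mitotic cyclin, rose by 0.68 (SE 0.0449, adjusted p = 1.74e-06), Top2a, a topoisomerase, by 0.66 (SE 0.0446, adjusted p = 2.1e-06), Mki67 by 0.63 and the replication helicase gene Mcm3 by 0.47. The single gene that fell was E2f2, by 0.72 (SE 0.032, adjusted p = 1.31e-07), while E2f1 rose by 0.45.

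Markers of other cell states went several ways beside these groups. Of 10 markers of undifferentiated myoblasts, Myf5 and Ccnd1 rose, Myod1, Des and Cdh15 fell and 5 did not pass (2 and 3 adjusted over the list alone; median 0.06, camera adjusted p = 0.647). Of 10 smooth muscle markers, 3 rose, 2 fell and 5 did not pass (3 and 2 adjusted over the list alone; median 0.09, camera adjusted p = 0.0595). The 3 were Cnn1, Actg2 (0.88, SE 0.0595, adjusted p = 1.98e-06), which is close in sequence to other actins, and Tagln (0.68, SE 0.0488, adjusted p = 3.13e-06). This list was called when Scr 2, Scr 5, shZc3h10 1 or shZc3h10 3 was left out (adjusted p = 0.0497, 0.0454, 0.0407 and 0.0477), and with the mean of each gene's probe sets (adjusted p = 0.0378). Of 9 fibroblast markers, 4 fell, 0 rose and 5 did not pass (4 and 0 adjusted over the list alone; median -0.07, camera adjusted p = 0.192), with Dcn, decorin, down by 0.63 (-0.63, SE 0.0516, adjusted p = 7.12e-06).

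**Figure D2:**
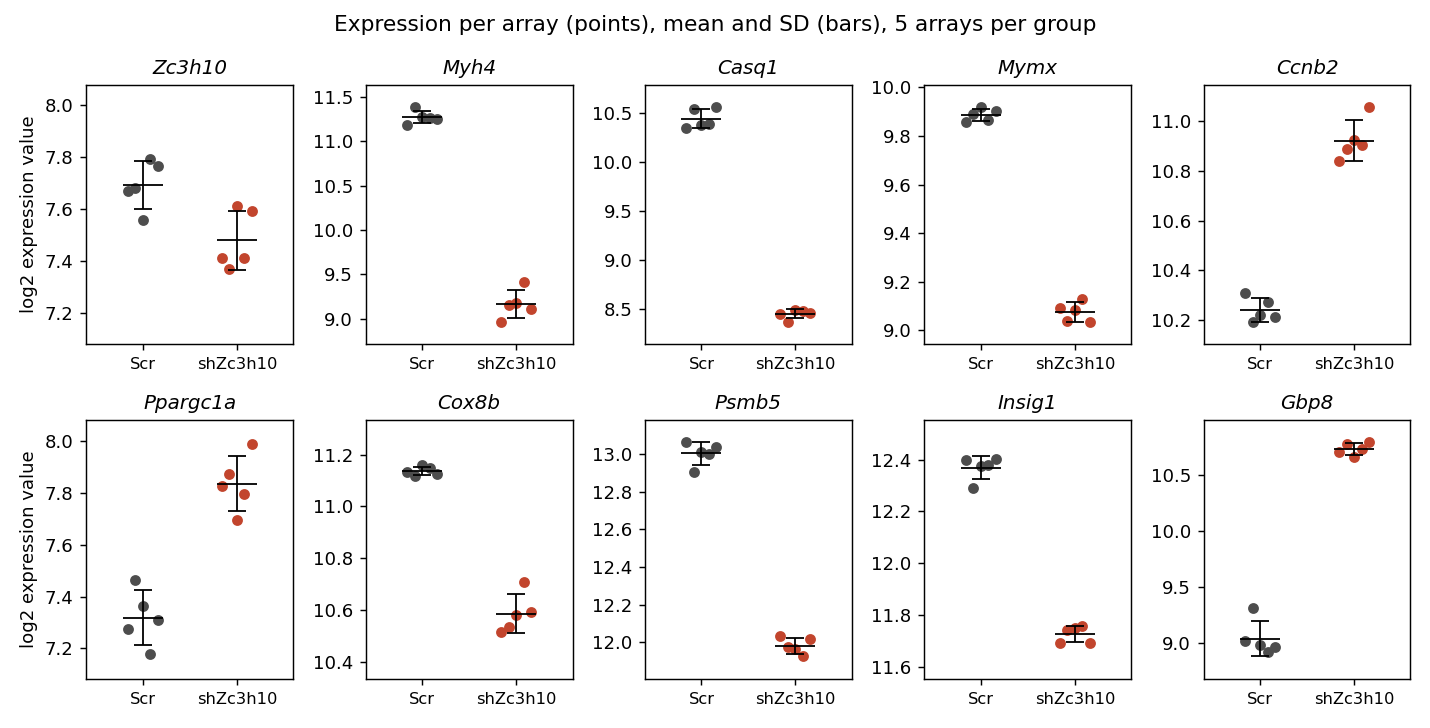
Log2 expression value (vertical axis, a separate range per gene) of 10 named genes on each of the 10 arrays, as points, with the mean and SD of 5 Scr and 5 shZc3h10 arrays. The groups overlap for Zc3h10, at 7.69 and 7.48, and not for the other genes shown, such as Myh4 at 11.27 and 9.16 and Gbp8 at 9.04 and 10.73.

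A part of the nuclear genes of the respiratory chain and ATP synthase fell by small amounts, while most did not pass. Of 46 complex I subunits and assembly factors, 18 fell, 1 rose and 27 did not pass (21 and 2 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.00198, but adjusted p = 0.184 with an estimated correlation). Ndufb8 fell by 0.44 (SE 0.0428, adjusted p = 2.15e-05), Ndufaf1 by 0.34 and Ndufv2 by 0.27, while Ndufv3 was up by 0.13. Of 35 genes of complexes II, III and IV, 14 fell, 0 rose and 21 did not pass (19 and 0 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 4.12e-05, but adjusted p = 0.0573 with an estimated correlation). Among the muscle isoforms of complex IV subunits, Cox7a1 fell by 0.59, Cox8b by 0.55 (SE 0.0399, adjusted p = 3.25e-06) and Cox6a2 by 0.30. Sdhd, a subunit of complex II, fell by 0.42 and the copper chaperone gene Cox17 by 0.33. Of 20 ATP synthase genes, 7 fell, 0 rose and 13 did not pass (7 and 0 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0288, but adjusted p = 0.0682 with an estimated correlation). Atp5pb fell by 0.21, Atp5g3 by 0.18 and Atp5k by 0.16, and the list's call was lost without Scr 5 (adjusted p = 0.0525).

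Genes encoded in the mitochondrial genome did not pass. Of the 10 measured, 0 passed the limma test over all genes, adjusted over the list alone or at an unadjusted p under 0.05, with a median of 0.02 (camera adjusted p = 0.437). ND2 had the smallest p, with a difference of 0.07 (SE 0.0363, adjusted p = 0.209), and passed with trended and robust moderation (adjusted p = 0.0343). The probe sets of 9 of the 10 lay near the top of the measured range, at mean values of 13.85 to 14.34, whereas ND6 read 9.54. The difference between nuclear and mitochondrial genes was not tested.

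Other mitochondrial groups also fell in part. In the mitochondrial ribosome, 21 of 68 genes fell, 2 rose and 45 did not pass (22 and 3 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.00145, but adjusted p = 0.0682 with an estimated correlation). Mrpl54 fell by 0.44 and Mrpl12 and Mrpl10 each fell by 0.33. Of 32 genes of protein import and mitochondrial chaperones, 14 fell, 2 rose and 16 did not pass (14 and 2 adjusted over the list alone), with a median of -0.10 (camera adjusted p = 0.000328, but adjusted p = 0.0882 with an estimated correlation). Grpel1 fell by 0.51 (SE 0.0481, adjusted p = 1.82e-05), its relative Grpel2 by 0.42 and Hspa9, the mitochondrial Hsp70 that both serve, by 0.32, while Timm8b was up by 0.33. Of 19 genes of mitochondrial dynamics and mitophagy, 7 fell, 1 rose and 11 did not pass (7 and 1 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.00514, but adjusted p = 0.0682 with an estimated correlation). Pink1, a kinase that marks damaged mitochondria, fell by 0.46 (SE 0.0402, adjusted p = 1.09e-05), and Opa1, which fuses inner membranes, and the cristae gene Apool each fell by 0.33.

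Among regulators of mitochondrial biogenesis and mtDNA maintenance, 10 of 27 genes fell, 2 rose and 15 did not pass (12 and 4 adjusted over the list alone), and the list was not called (median -0.09, camera adjusted p = 0.065), although it was called without shZc3h10 5 (adjusted p = 0.0317) and after cyclic loess (adjusted p = 0.0358). Ppargc1a, the coactivator PGC-1alpha, rose by 0.52 from 7.32 ± 0.107 to 7.83 ± 0.106 (SE 0.0639, adjusted p = 0.000132). The related Ppargc1b fell by 0.27, Gabpa, a transcription factor for nuclear genes of the respiratory chain, by 0.42 (SE 0.0304, adjusted p = 3e-06), Esrra by 0.15 and Tfam, which packages mtDNA, by 0.11. Prkaa2, a catalytic subunit of AMP-activated kinase, fell by 0.43.

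Genes of the TCA cycle, glycolysis and fatty acid oxidation fell in part. In the list of the TCA cycle and pyruvate dehydrogenase, 15 of 25 genes fell, 2 rose and 8 did not pass (17 and 3 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 8.2e-06, but adjusted p = 0.0573 with an estimated correlation). The largest changes were those of regulators of pyruvate dehydrogenase. Pdpr fell by 0.56 (SE 0.0425, adjusted p = 4.43e-06) and the kinase gene Pdk2 by 0.44 (SE 0.0329, adjusted p = 3.94e-06), whereas the kinase gene Pdk3 rose by 0.57 (SE 0.0437, adjusted p = 4.46e-06). The catalytic subunit gene Pdha1 fell by 0.31. Of 20 glycolysis genes, 8 fell, 2 rose and 10 did not pass (12 and 3 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0124, but adjusted p = 0.0573 with an estimated correlation). Slc2a4, the insulin-responsive glucose transporter GLUT4, fell by 0.73, the muscle phosphofructokinase gene Pfkm by 0.63 (SE 0.0504, adjusted p = 5.94e-06) and Tpi1 by 0.35. Of 24 genes of fatty acid oxidation, 7 fell, 3 rose and 14 did not pass (7 and 3 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.0267, but adjusted p = 0.0682 with an estimated correlation). Among its members, the fatty acid transporter gene Cd36 fell by 1.02 to 9.98 ± 0.0702 (SE 0.0592, adjusted p = 7.61e-07). Cpt1a, which encodes a carnitine palmitoyltransferase and is not the only such gene in the list, rose by 0.49 (SE 0.0318, adjusted p = 1.5e-06). The fatty acid oxidation call was also lost after quantile normalisation (adjusted p = 0.0509) and with the filter on dim genes (adjusted p = 0.0581). The share of fatty acid oxidation genes that fell was close to that among all genes at similar levels.

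Cholesterol biosynthesis fell without exception among called genes. Of 18 genes, 15 fell, 0 rose and 3 did not pass (15 and 0 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.18e-10, and adjusted p = 0.00305 with an estimated correlation). Stard4, a sterol carrier, fell by 0.66 (SE 0.0454, adjusted p = 2.27e-06), Insig1, a sterol-regulated protein of the endoplasmic reticulum, by 0.64 (SE 0.0339, adjusted p = 3.99e-07), Dhcr7 by 0.61 and Hmgcs1 by 0.47. Srebf2, the transcription factor of the pathway, did not pass, at -0.01 (adjusted p = 0.923).

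Most proteasome genes fell, while a majority of endoplasmic reticulum chaperone genes rose. Of 33 proteasome genes, 24 fell, 0 rose and 9 did not pass (26 and 0 adjusted over the list alone), with a median of -0.16 (camera adjusted p = 2.96e-11, and adjusted p = 0.00677 with an estimated correlation). Psmb5, the chymotrypsin-like catalytic subunit, fell by 1.02 from 13.00 ± 0.0595 to 11.98 ± 0.0426 (SE 0.0385, adjusted p = 5.37e-08), while the next largest falls were those of Psmc5 by 0.50 and Psma3 by 0.44. Of 21 endoplasmic reticulum chaperone genes, 12 rose, 2 fell and 7 did not pass (15 and 2 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 9.68e-05, and adjusted p = 0.0329 with an estimated correlation). Edem1, which targets misfolded proteins for degradation, was up by 0.42 (SE 0.0345, adjusted p = 7.43e-06), Dnajb9 by 0.40 and Herpud1 by 0.32, and Derl1 and Pdia6 fell by 0.16 and 0.14. Of 48 cytosolic ribosomal protein genes, 10 rose, 0 fell and 38 did not pass (5 and 0 adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.0124, but adjusted p = 0.185 with an estimated correlation). Rpl28 was up by 0.18 (adjusted p = 0.000953) and Rpl4 by 0.14 (adjusted p = 0.00332), and the list's call was lost with the filter on dim genes (adjusted p = 0.0665). The share of ribosomal protein genes that rose was no higher than among all genes at similar levels.

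A part of the matrix genes rose. In the extracellular matrix list, 17 of 32 genes rose, 2 fell and 13 did not pass (18 and 2 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 4.05e-07, but adjusted p = 0.0598 with an estimated correlation). Tnc, tenascin C, was up by 0.64 (SE 0.0306, adjusted p = 2.37e-07), the fibrillar collagen genes Col5a2 by 0.58 (SE 0.0341, adjusted p = 8.39e-07) and Col1a1 by 0.56, and Thbs1, thrombospondin, by 0.51. The members that fell were Dcn, by 0.63, and Col6a2, by 0.11.

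A part of the interferon-induced genes rose. Of 37 genes of the interferon and antiviral list, 9 rose, 2 fell and 26 did not pass (9 and 2 adjusted over the list alone), with a median of 0.08 (camera adjusted p = 0.00448, but adjusted p = 0.055 with an estimated correlation). Oasl2, a relative of the oligoadenylate synthetases, was up by 0.86 (SE 0.063, adjusted p = 3.49e-06), Ddx58, the cytosolic RNA sensor RIG-I, by 0.75 (SE 0.0512, adjusted p = 2.07e-06) and Rtp4 by 0.35, whereas Stat2 fell by 0.26. Of 22 NF-kB and inflammatory genes, 6 rose, 3 fell and 13 did not pass (6 and 3 adjusted over the list alone), and the list was not called (median 0.02, camera adjusted p = 0.0827). Csf1 was up by 0.57 (SE 0.0367, adjusted p = 1.43e-06), Ptgs2, the inducible cyclooxygenase, by 0.54 (SE 0.0401, adjusted p = 3.89e-06) and the chemokine gene Ccl2 by 0.54 (SE 0.0828, adjusted p = 0.000588).

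Of the 36 lists, 19 were called with the preset correlation, 5 of them higher and 14 lower. With an estimated correlation 6 held, those of the cell cycle, the sarcomere, excitation-contraction coupling, the proteasome, cholesterol biosynthesis and endoplasmic reticulum chaperones. Of the 19, 4 had medians inside the range of lists matched on level that leaves out 2.5% at each end, namely ATP synthase (percentile 6.1), mitochondrial dynamics (4.87), fatty acid oxidation (3.14) and cytosolic ribosomal proteins (94.3). Of the 17 lists not called, 3 had medians below that range, namely mitochondrial biogenesis (1.3) and the macrophage (0.34) and osteoblast (0.68) markers.

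**Figure D3:**
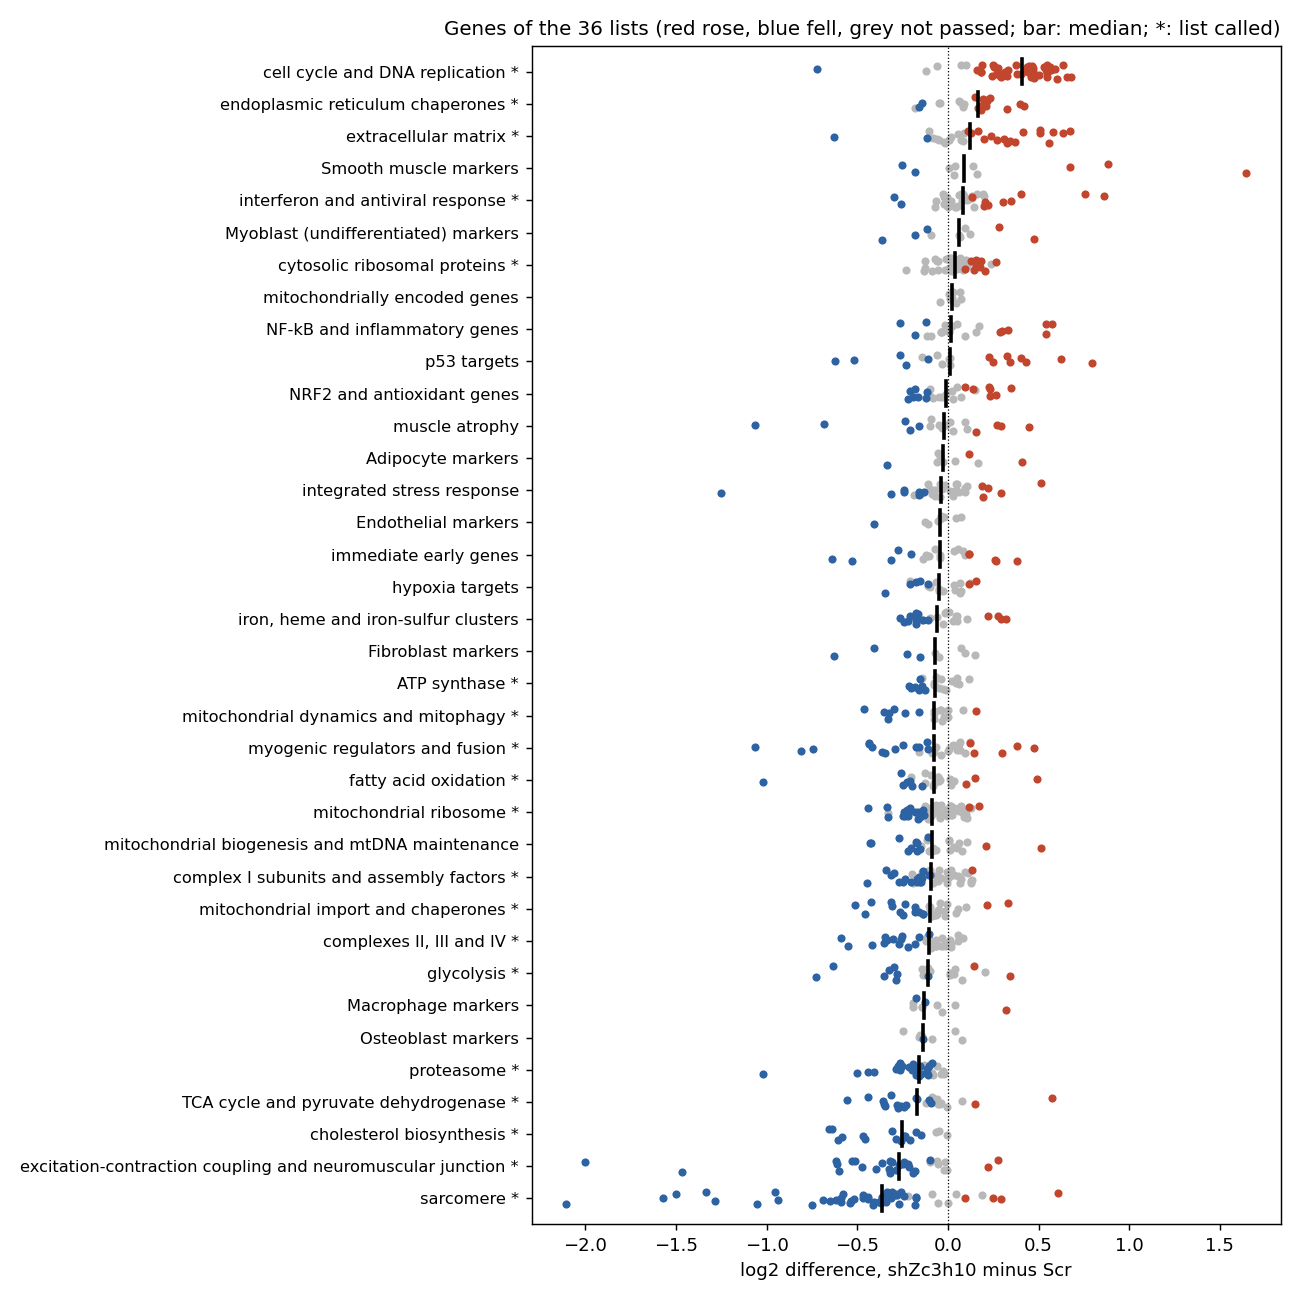
Log2 difference (shZc3h10 minus Scr, horizontal axis) of each measured gene of the 36 lists, 1 list per line ordered by its median (black bar); red genes rose, blue genes fell and grey genes did not pass, and a star marks the 19 lists called with the preset correlation. The medians run from -0.36 for the sarcomere to 0.41 for the cell cycle.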

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

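Of the tests in this part, those of signal level, mislabelling, dilution, myoblast markers, level-matched lists and saturation were chosen after the results were seen; those without the muscle isoforms and of other splits of the arrays were chosen before, except the splits with an estimated correlation, which were added after.

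In 14 of 242 groups of 5 arrays examined for the named genes, 1 array stood apart from the other 4 by a gap that chance gives in about 1 group in 20, so that about 12.1 were expected. In Scr these were Gbp8 at 9.32, Atp2a1 at 12.73 and Insig1 at 12.29 on Scr 2, Gclc at 10.35 on Scr 3, and Ndufb8 at 8.74 and Tagln at 10.62 on Scr 5. In shZc3h10 they were Tspan32 at 8.94, Grpel1 at 9.71 and Gpx1 at 9.64 on array 1, and Cpt1a at 10.85, Pfkm at 11.26, Actn2 at 10.47, Rplp0 at 12.27 and Rpl4 at 13.54 on array 5. Outside the genes of the report, 618 of 17824 probe sets without a single gene symbol were higher in shZc3h10 (limma adjusted p under 0.05) and 571 were lower.

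The targeted transcript fell by only 13.8% while 5548 genes were called. Compression of every change by background at this signal level is argued against. Of 1152 other genes within 0.25 of the Zc3h10 level in Scr, 25 fell past the threshold by over 0.5 on the log2 scale. These genes do not show how far the Zc3h10 probe set itself is compressed. A mislabelled array is also argued against, since 0 arrays correlated best with an array of the other group. A probe set of Zc3h10 that binds other transcripts too, a loss of protein beyond that of the RNA, and effects of the 1 hairpin on other targets all stay open, untested. As to chance, 1 of 100 splits of the 10 arrays (of 126 possible), the real one, gave as many genes as the 5548 called, and the highest of the others gave 1.

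Contractile genes fell while cell cycle genes rose. A uniform dilution of myotube transcripts, which lowers them all by the same factor, is argued against, as the SD of the differences of 43 contractile genes at levels between 8 and 12 was 12.9 times their median SE. A larger share of undifferentiated myoblasts cannot be told apart from a change within myotubes, because the myoblast markers went both ways (median 0.06) and myotubes express several of them. A lower share of myotubes in which unfused cells also express part of the contractile genes, and the biological explanation that the Zc3h10 hairpin hinders differentiation, both stay open.

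Of 101 nuclear genes of the respiratory chain and ATP synthase, 39 fell and 1 rose, while 0 of 10 mitochondrially encoded genes passed the limma test. A bias that depends on signal level is argued against, since their median of -0.095 lay below those of all 10000 lists matched on level, of which the lowest was -0.072. The muscle isoforms Cox6a2, Cox7a1 and Cox8b alone are argued against, as the other 98 genes, pooled, still passed (camera p = 3.71e-06, and p = 0.0394 with an estimated correlation, unadjusted). With an estimated correlation, camera called none of the lists that were pooled. Their adjusted p was 0.184 for complex I, 0.0573 for complexes II, III and IV and 0.0682 for ATP synthase. For the mitochondrially encoded genes, saturation may hide a change, since their median level lay at percentile 99.96 of all genes, and ND6, at 9.54, had a wider error (0.07, SE 0.149). The biological explanation, that the Zc3h10 hairpin lowers nuclear and not mitochondrial transcripts of the same complexes, stays open for that reason, and the difference between them was not tested. A lower share of myotubes or hindered differentiation, both left open above, could also lower these nuclear genes. The design cannot tell these apart from an effect on mitochondrial genes alone.

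For the gene lists, 2 of 100 splits, the real one included, called as many as the real 19, and the highest other split called 20, with a median of 3 over the other splits. That share lies under 0.05, the limit set beforehand, but another split called more lists than the real one. The count of lists therefore does not exclude chance by itself. With an estimated correlation, the real split called 6 lists and the highest of the other splits called 0.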

How the results depend on the processing

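Of the alternatives, 0 were chosen after the results were seen. The Zc3h10 difference kept its sign in every setting run and ranged from -0.1863 (without shZc3h10 2) to -0.2483 (without Scr 3) as each array was left out; the call was lost without Scr 4, Scr 5, shZc3h10 1, shZc3h10 2 or shZc3h10 4, where fewer samples were fitted. Same-numbered arrays showed no shared deviation over all genes (r = -0.011 to 0.023). The labels state no pairing, and these values do not exclude one. With the replicate number as a block, Zc3h10 stayed at -0.2141 with adjusted p = 0.0678, against 0.0165 to 0.047 over the other fits, scalings and probe set rule on all 10 arrays. The block gave 2355 genes higher, 2409 lower and 18 lists called. Of 4764 genes called with the block, 4563 were called in the same direction without it. A fold of at least 1.5 left 122 genes higher and 242 lower, by its construction. The number of lists called was 6 with an estimated correlation, 31 with fry and 31 with an exact permutation, against 19; the latter 2 do not compare a list with other genes. The other counts stayed within 1.5 times the reported ones; leaving out each array gave 2436 to 2730 genes higher and 2478 to 2810 lower. For the named genes other than Zc3h10, 2244 of 2276 values under the alternatives kept their side of the threshold, 31 fell below it and 1, ND2, passed it. Of 752 list results, 696 kept their side, 25 fell below and 31 passed it. Among genes and lists, 0 changed sign where the main or the alternative result passed the threshold. A change of sign between results that both did not pass was not counted. Calls lost under the block or without single arrays included those of Itgam, Lpl, Cx3cr1, Sox9, Bnip3 and Cd34, and that of Rplp0 was lost with the mean of its probe sets; the causes were not tested. The ordinary linear model gives no list test. The median difference of all genes stayed between -0.020 and -0.001. Near the background and near saturation, signal limits what could be detected.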

Other observations

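Of the tests in this part, that of cilium genes was prompted by the Ift and Bbs results but chosen before the values of its own genes were seen; the scan of gene families, the cilium test without members of the same complexes, and the tests of fibre types, complex IV isoforms and interferon genes were chosen after the results were seen.

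Several fixed lists showed changes of single genes while camera, which compares a list with other genes, did not call the list. Of these 7, all but that of NRF2 were called by fry and by the exact permutation of the list mean, which make no such comparison. Of 33 genes of the integrated stress response, 5 rose, 8 fell and 20 did not pass (6 and 11 adjusted over the list alone; median -0.04, camera adjusted p = 0.444), with Fgf21, a hormone induced by mitochondrial stress in muscle, down to 9.30 ± 0.0824 from 10.54 ± 0.076 (SE of the difference 0.0507, limma adjusted p = 8.98e-08) and Sesn2 up by 0.52. Of 18 atrophy genes, 4 rose, 5 fell and 9 did not pass (4 and 5 adjusted over the list alone; median -0.02, camera adjusted p = 0.689), with Mstn at -1.07, the ubiquitin ligase gene Trim63 at -0.68 and the other muscle ligase Fbxo32 at 0.27. Of 19 p53 targets, 8 rose, 5 fell and 6 did not pass (8 and 5 adjusted over the list alone; median 0.01, camera adjusted p = 0.237), with Trp53inp1 at 0.80 and Pmaip1 at -0.62. Of 25 NRF2 and antioxidant genes, 7 rose, 7 fell and 11 did not pass (7 and 8 adjusted over the list alone; median -0.01, mean 0.01, camera adjusted p = 0.934), with Mt1 at 0.35. Of 27 iron, heme and iron-sulfur genes, 4 rose, 11 fell and 12 did not pass (5 and 12 adjusted over the list alone; median -0.06, camera adjusted p = 0.139), with Fth1 at -0.22, Tfrc at -0.21 and Slc11a2 at -0.24. Of 21 immediate early genes, 5 rose, 5 fell and 11 did not pass (5 and 8 adjusted over the list alone; median -0.05, camera adjusted p = 0.437), with Klf4 at -0.64 and Klf2 at -0.53. Of 20 hypoxia targets, 2 rose, 5 fell and 13 did not pass (3 and 7 adjusted over the list alone; median -0.05, camera adjusted p = 0.437), with Pdk1 at -0.35.

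Most markers of macrophages, endothelium, osteoblasts and adipocytes did not pass. These lists had median levels of 6.06 to 6.45, where calls were rarer than the 25% over all genes. Of 10 equal parts of the genes by level, part 4, at a mean of 6.285, held 81 rises and 100 falls. Some called markers were clearly expressed in Scr, with means of 9.99 for Sox9, 9.78 for Lpl and 9.28 for Pparg. Camera called none of these lists. The macrophage and osteoblast lists were called by fry (adjusted p = 0.0263 and 0.0435) and by the exact permutation (adjusted p = 0.0276 each). The endothelial and adipocyte lists were called by neither. Of 10 macrophage markers, 1 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone (median -0.13, camera adjusted p = 0.407). Of 10 endothelial markers, 0 rose and 1, Cldn5, fell (-0.41, adjusted p = 0.00334), also adjusted over the list alone (median -0.04, camera adjusted p = 0.437). Of 8 genes of the osteoblast list, 0 rose and only Sox9 fell (-0.136, adjusted p = 0.0204), also adjusted over the list alone (median -0.14, camera adjusted p = 0.309). Of 9 adipocyte markers, 2 rose, 1 fell and 6 did not pass, also adjusted over the list alone (median -0.03, mean 0.02, camera adjusted p = 0.62), with Pparg at -0.33 and Cebpa at 0.41.

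A part of the primary cilium genes rose. A scan of 339 families of at least 8 genes that share the letters of their symbol called 8 of them with camera, 5 higher and 3 lower, and 0 with an estimated correlation. Among the 5 were the intraflagellar transport genes Ift, of which 8 of 14 rose and 0 fell (median 0.15, camera adjusted p = 0.00326), and the Cep genes of the centrosome, of which 14 of 39 rose and 2 fell (camera adjusted p = 0.00656); of the Bbs genes, 5 of 8 rose and 0 fell but the family was not called (camera adjusted p = 0.0645). The hypothesis of a rise of primary cilium genes was then tested on 35 other genes of the cilium and its transition zone, of which 28 were measured. Of these, 17 rose, 0 fell and 11 did not pass, with a median of 0.13 (camera p = 5.65e-09, and p = 0.00384 with an estimated correlation). Invs was up by 0.70 (SE 0.0942, adjusted p = 0.000242), Tmem231 by 0.42 (SE 0.0386, adjusted p = 1.51e-05), Tmem107 by 0.40 and Tulp3 by 0.36. Of the 28, 6 belong to the same complexes as Ift and Bbs proteins under other symbols, and 4 of these rose (Wdr19, Wdr35, Ttc21b and Ttc8). Without the 6, a division made after the values were seen, 13 of 22 genes rose and 0 fell (median 0.12, camera p = 2.15e-07, and p = 0.0051 with an estimated correlation). This is consistent with a rise beyond the Ift and Bbs complexes, as a hypothesis, and its cause was not tested.

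Beside the muscle isoforms of complex IV subunits Cox6a2 (-0.30), Cox7a1 (-0.59) and Cox8b (-0.55), their ubiquitous partners, chosen after these values were seen, did not pass. Cox6a1 read 0.02 (SE 0.03), Cox7a2 -0.03 (SE 0.041) and Cox8a 0.06 (SE 0.04). Cox6a1 and Cox8a lie near the top of the range, at 13.37 and 12.97 in Scr, where changes are understated. Within arrays the partners differed by -0.32, -0.57 and -0.61 (exact two-sided permutation p = 0.0079 each, the smallest possible), but the pairs were picked because the muscle forms fell, so these p-values are no independent evidence.

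Myh4, Casq1, Mybpc2, Myoz1 and Pvalb were among the largest falls. A larger fall of fast fibre isoforms was therefore put to a test over 10 pairs of a fast form and a counterpart taken as slow. The fast form was the lower in 7 pairs (exact binomial p = 0.344, two-sided), but Myh4, Casq1, Mybpc2 and Myoz1, which prompted the test, are 4 of them. In the other 6 pairs the fast form was the lower in 3, so the pairs do not decide on the hypothesis. Casq1 and Casq2 differed most in its favour (-2.00 and -0.22). Actn3 and Actn2 differed the other way (-0.28 and -1.33), but Actn2 is not confined to slow fibres, so this pair is a poor test.

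The rise of Gbp genes, of which 6 of 10 rose and 0 fell (median 0.61, camera adjusted p = 0.00149 over the families, but adjusted p = 0.563 with an estimated correlation), was set beside the interferon list without any Gbp gene. Those 36 genes had a median of 0.09 (camera p = 0.00135, and p = 0.0121 with an estimated correlation, unadjusted), and 9 rose and 2 fell. This list differs by 1 gene from the list of the report, so its outcome was known beforehand, and it does not decide whether a general rise of interferon-induced genes is part of the cause. All samples received adenovirus, and whether the viral doses matched in effect was not measured here.

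The proteasome's transcription factor gene Nfe2l1, chosen after its value was seen, fell by 0.46 beside its target genes, and the chaperonin genes Cct fell in 6 of 9 cases with 0 rises (median -0.15, camera adjusted p = 0.0312 over the families, but adjusted p = 0.734 with an estimated correlation).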
